A study of Anas platyrhynchos with 6 samples.

How the data were processed

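Ovaries of Jinding ducks, a Chinese laying breed of the domestic duck (Anas platyrhynchos), were profiled by RNA sequencing. Per the labels' protocols, the ducks came from a half-sib family, were kept in the same way to an age of 340 days and had their eggs recorded each day. A laying rate above 99% placed a duck in the high-production group and a rate below 85% placed it in the low-production group. Per the labels' protocols, ovaries were frozen on dry ice, RNA was extracted with Trizol, and libraries were made with a stranded Illumina TruSeq mRNA kit, which selects polyadenylated RNA. There were 3 libraries in each of 2 groups, 6 libraries in all. The labels do not state that each library came from a separate duck, so p-values measure the spread between these samples, part of which can be technical. Libraries are named high 1 to 3 and low 1 to 3 in the order of the sample records, and these numbers do not pair libraries across groups. The sample titles number them 1, 2 and 4 (high) and 5, 7 and 8 (low); any libraries with the numbers between were not analysed here.

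Per the submitters' processing notes, Bowtie2 version 2.0.6 and TopHat2 version 2.0.9 were used. The program that turned alignments into abundances, the genome build and the annotation are not given in the sources used here. Each deposited table held 1 value for each of 41952 RefSeq transcripts, 30690 with protein-coding or curated accessions (XM and NM) and 11262 with non-coding ones (XR). The tables name no unit. The deposited values were fractional, were never negative and summed to between 569606 and 639135 per library, a sum that differs between libraries as TPM values would not, so they were read as FPKM (fragments scaled by transcript length and library size). The unit FPKM is thus an inference from the deposited values. Some transcripts had values as small as 1.03e-104 FPKM, far below the worth of 1 fragment, as arises where reads are divided between overlapping transcripts by estimation.

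The depth of each library is unknown, because no read counts were used here. Low values were searched for steps of whole reads by comparing each library with high 1 over 7376 transcripts. These stayed under 1 FPKM, and above a very small minimum value, in every library. The fullest bin of the log2 ratios, 0.02 wide, held between 0.746% and 1.02% of the transcripts, so there was no common step and no count test was run. Precision was therefore taken from the replicates alone. The median standard error of a log2 difference was 0.261, which gives a 95% interval of 0.608 on either side of the typical difference.

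Gene symbols came from a RefSeq gene table of the telomere-to-telomere Pekin duck assembly of IASCAAS, matched by accession. With the version number included 5 transcripts matched, and without it 4636 matched, or 11.1% of all. Of the matched transcripts 3452 carried a gene symbol, covering 2325 distinct symbols, and 1184 carried only a placeholder name and were treated as unnamed. No coordinates were taken from this table, because the build behind the deposited values is not given in the sources used here. The other transcripts entered every test under their own accession and no name was guessed for them. All statements on named genes and gene lists therefore cover 2188 of the 19790 tested transcripts, or 11.1%.

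Values were transformed to log2(FPKM + 1). Transcripts with at least 1 FPKM in at least 3 libraries were tested, 19790 in all. Fold changes are on this log2(FPKM + 1) scale, high minus low, which understates the change of low transcripts. The high and low groups were compared with limma-trend (limma 3.58.1 in R 4.3.3), with group as the only term and no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, two-sided. The 27 gene lists, covering ovarian pathways and the cell types that a piece of ovary can hold, were fixed from textbook knowledge before the data were examined, as were the grouping, the test, the rule for named genes and the alternatives unless stated otherwise. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera with a correlation estimated per list and limma's fry were the alternatives. Of the 653 list entries 98 were tested, from 95 distinct genes, so some genes stood in more than 1 list. A gene with several tested transcripts entered a list through its most abundant one.

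The rule for named genes took, because fewer than 5 genes were called in each direction, the 5 transcripts with a symbol and the smallest p in each direction. It also took up to 4 members with the smallest p in each gene list, reduced to 1 after the data were examined for lists with fewer than 5 tested members, and 17 reproductive genes whatever their values. Some list members that this rule takes are not reported here. Of those 17 genes, 4 had a name in the tables and all 4 were tested. The transcript XM_013092159.1, which has no symbol, and the other members of lists and isoforms given below were chosen after their values were seen. Isoform shares were tested after the data were examined, for genes with at least 2 tested transcripts: the log2 odds of each transcript against the other transcripts of its gene, with a pseudocount of 1, went into the same limma model.

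Library similarity was described by Pearson and Spearman correlation of the log2 values and by principal components. The alternatives were array weights, no variance trend, quantile normalization, median centring of libraries, no filter, a minimum of 5 FPKM, pseudocounts of 0.1 and 0.01, robust empirical Bayes, other thresholds, sums per gene, and each library left out in turn with the tested transcripts kept. The procedures were tested on simulated data with known changes, drawn for the comparison of high with low over 19261 transcripts. The test recovered 28.6% of transcripts changed by 1 on the log2 scale, 94.0% of those changed by 2 and 98.0% of those changed by 3, with 9 false calls among 169. The simulation gave both groups the same spread, while the median SD in the data was 0.219 in high and 0.335 in low libraries. It also held many true changes, which loosens the adjusted threshold. These rates can therefore overstate recovery in the data, where few transcripts may differ. Over 30 simulated draws of the leukocyte list, camera called 30 when its 12 members were shifted by 0.6 and 0 when they were not. These draws varied each member independently, while the correlation estimated for this list in the data was 0.560. The 0 calls therefore do not test the preset correlation of 0.01. For isoform shares over 824 isoforms, 30 of 30 simulated changes of 3 in log2 odds were recovered with 4 false calls. These draws also used the same spread in both groups, varied isoforms independently and held many true changes, so they can overstate recovery. In the data an EXTL2 isoform with a difference of -3.37 in log2 odds (SE 0.637) was not called (limma adjusted p = 0.262). Figures were drawn with matplotlib 3.10.9.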

Results

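Ovarian transcript abundance was compared between Jinding ducks of high laying rate (above 99%) and low laying rate (below 85%), all 340 days old, with 3 libraries per group. The question set by the design was which ovarian transcripts differ between ducks that lay almost daily and ducks that lay less often. Abundance was read in FPKM for 41952 transcripts, and read depth is unknown. Summed FPKM was 622708, 637486 and 639135 in the high libraries and 593358, 569606 and 605510 in the low libraries. Between 18968 and 19712 transcripts reached 1 FPKM in a library. Values below are means ± SD in FPKM with n = 3 per group, unless a library is named.

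The ovaries of the high-production ducks resembled one another more closely than those of the low-production ducks. Pearson correlations between high libraries were 0.958 to 0.960, and those between low libraries were 0.899 to 0.940, with low 1 and low 3 the least alike. Mean correlation was 0.959 within the high group and 0.926 within the low group, a gap of 0.0328, with p = 0.1 in a two-sided exact permutation test over 20 labelings. That is the smallest p this test can give with 3 libraries against 3. The first principal component, 36.1% of the variance, ran between low 1 at 54.9 and low 3 at -62.5. The second, 19.3% of the variance, set the high libraries at -13.8, -27.7 and -25.9 against the low libraries at 17.6, 41.6 and 8.25. No library was a copy of another.

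**Figure D1:**
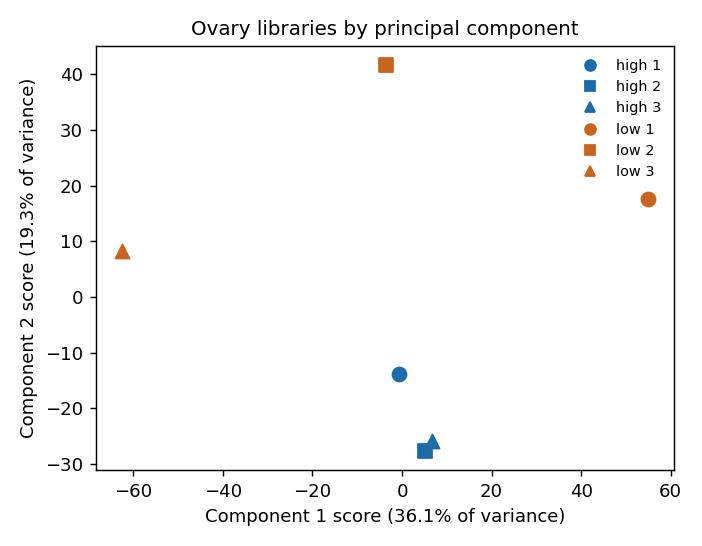
Scores of the 6 ovary libraries on principal components 1 and 2 of log2(FPKM + 1) over the tested transcripts; blue points are high-production and orange points low-production libraries, with 1 marker shape per replicate. The high libraries lie together at the bottom, and low 1 and low 3 lie at opposite ends of component 1, at 54.9 and -62.5.

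A single transcript passed the test between the groups, and no gene with a symbol did. XM_013092159.1, to which no gene name could be matched, was almost absent from the high ovaries, at 0.00011, 0.271 and 0.246 FPKM, and abundant in the low ovaries, at 89.5, 204 and 176 FPKM. Its group means were 0.172 ± 0.150 and 156 ± 59.7 FPKM, a log2 difference of -6.99 (SE 0.318, limma adjusted p = 0.000786). The difference held in all 6 fits that left out a library. Without a filter on abundance, with 39755 transcripts tested, the log2 difference was again -6.99 (SE 0.339), but it missed the threshold (limma adjusted p = 0.121). With values near 0 in the high group, the size of the difference depends on the pseudocount: it was -9.30 (SE 0.566) at 0.1, still called, and -10.68 (SE 1.23) at 0.01, with a larger error and no call (limma adjusted p = 0.491). Across its alternatives on complete groups and with a library left out, the log2 difference kept its sign.

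Of 19790 transcripts tested, 0 were called higher and 1 was called lower in the high group by limma-trend. At an unadjusted p under 0.05 there were 694 transcripts, 334 higher and 360 lower, where 989.5 would be expected with no difference. Other splits of the 6 libraries into 3 and 3, which mix the groups, gave between 362 and 1730 such transcripts. The second smallest adjusted p by limma was 0.242. Limma called 2 transcripts without high 1, low 1 or low 2 and 3 without low 3. The libraries of the groups did not overlap for 1691 transcripts, or 8.54%, where chance gives 10% for 3 libraries against 3. The median log2 difference over all tested transcripts was -0.003. Among the 2188 transcripts with a symbol, 0 passed when adjusted over those alone, with a smallest limma adjusted p of 0.163. With array weights, which let each library count by its estimated reliability, limma called 2292 transcripts, 1115 higher and 1177 lower. Those weights gave low 2 97.1% of the weight of its group, and leaving out any library brought the weighted count to between 1 and 11.

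Among named genes, CYB5R4, a cytochrome b5 reductase of the endoplasmic reticulum, had the smallest p of those higher in the high group. Its transcript XM_005013063.2 was at 5.92 ± 1.68 in high and 0.632 ± 0.0483 in low ovaries, a log2 difference of 2.05 (SE 0.265, limma adjusted p = 0.295). RGS1, a regulator of G-protein signalling prominent in lymphocytes, was at 32.2 ± 5.13 against 13.7 ± 0.186, a log2 difference of 1.16 (SE 0.171, limma adjusted p = 0.451). SNRNP35, a protein of the minor spliceosome, differed by 1.05 (4.96 ± 1.24 against 1.84 ± 0.265). The homeobox gene ALX1 differed by 1.06 (3.66 ± 0.937 against 1.23 ± 0.314), and CAPN6, a calpain-family gene, by 0.92 (6.55 ± 1.06 against 3.03 ± 0.765). For each of these 5 transcripts every high library was above every low library, but none passed the threshold. CYB5R4, SNRNP35 and CAPN6 had other tested transcripts, so these values do not describe the whole gene.

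On the other side, EXTL2, a glycosyltransferase of the exostosin family, had the smallest p. Its transcript XM_005018759.2 was at 1.90 ± 0.305 in high and 15.1 ± 8.07 in low ovaries, a log2 difference of -2.30 (SE 0.441, limma adjusted p = 0.9998). Without low 3, in which it stood at 5.76 FPKM, it passed, with a log2 difference of -2.84 and a limma adjusted p of 0.0350. CMBL, a hydrolase, was at 5.64 ± 3.33 against 33.4 ± 23.3, a log2 difference of -2.30. SGMS2, a sphingomyelin synthase, was at 5.61 ± 0.480 against 10.7 ± 2.17, a log2 difference of -0.81. EVI5, a regulator of Rab GTPases, was at 1.75 ± 0.174 against 3.98 ± 0.801, a log2 difference of -0.85. A transcript of the actin-binding gene CALD1, XM_005017091.2, was at 2.67 ± 1.82 against 13.7 ± 9.16, a log2 difference of -1.92. It was a minor transcript, at 1.49% of the summed matched CALD1 transcripts in high and 6.16% in low ovaries. The CALD1 sums overlapped between the groups, at 169 ± 31.3 against 208 ± 56.1. These 5 transcripts were lower in every high library than in every low library, and none passed in the comparison of all 6 libraries. Array weights brought all 10 named transcripts past the threshold, under the weights described for low 2, and likewise GDF9, BMPR2, BOK, EPSTI1, COX7A2, RPL7, TDRD5, DPT, SPI1 and APOH.

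**Figure D2:**
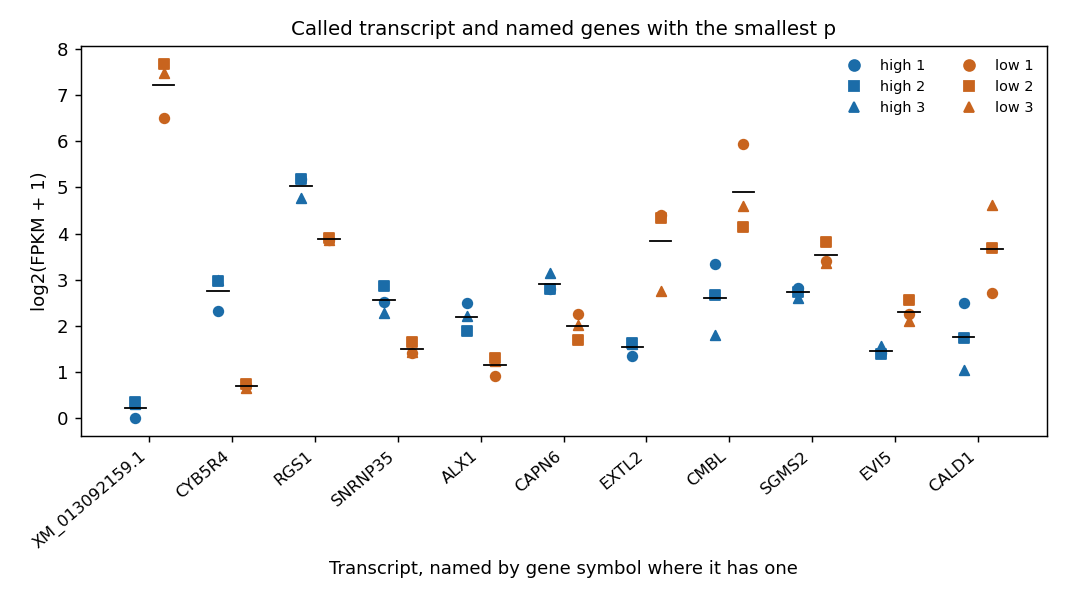
Abundance of the called transcript and of the 5 named transcripts with the smallest p in each direction, as log2(FPKM + 1) on the vertical axis; each point is 1 library, blue for high and orange for low production, and black lines are group means of 3 libraries. The groups do not overlap for any of them, yet only the unnamed transcript, at a log2 difference of -6.99, passed the test.

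Of the reproductive genes set for naming, the 4 that were tested did not pass the threshold. FSHR, the follicle-stimulating hormone receptor, was at 15.3 ± 2.54 in high and 16.7 ± 1.62 in low ovaries, a log2 difference of -0.13 (95% interval -0.56 to 0.30). CYP19A1, the aromatase that makes estrogens, was at 34.9 ± 9.74 against 26.1 ± 13.6, a difference of 0.50 (-0.43 to 1.44). With a library left out, the CYP19A1 difference ran from 0.082 (without low 3) to 0.87 (without low 1). FST, the activin-binding protein follistatin, was at 35.3 ± 5.75 against 35.1 ± 7.31, a difference of 0.015 (-0.46 to 0.49), and GDF9, an oocyte growth factor, was at 58.7 ± 3.60 against 69.1 ± 17.7, a difference of -0.20 (-0.69 to 0.29). With array weights GDF9 passed, at -0.49 (limma adjusted p = 0.0402). The unweighted intervals of FSHR, FST and GDF9 exclude a doubling in either direction on the log2(FPKM + 1) scale, and that of CYP19A1 does not. The other 13 of the 17 reproductive genes set for naming were not analysed here.

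The genes fixed for gonadotropin and gonadal peptide signalling were lower in high ovaries for 5 of 6 tested members and higher for 1, with a median log2 difference of -0.13. The list was not called (limma camera adjusted p = 0.101). BMPR2, a receptor for bone morphogenetic proteins, had the smallest p of them, at 11.9 ± 3.19 against 19.7 ± 3.53 and a log2 difference of -0.69 with an unadjusted limma p of 0.0193. BMP7 was at 15.6 ± 3.19 against 17.3 ± 3.42, and the activin receptor ACVR2A at 16.1 ± 1.21 against 17.5 ± 2.69. The list was called lower in high without high 3 (limma camera adjusted p = 0.0400) and with a minimum of 5 FPKM (limma camera adjusted p = 0.0473). With an estimated correlation the limma camera adjusted p in these settings was 0.336 and 0.445, and 0.463 in the comparison of all libraries. The estimates were 0.0481, -0.103 and 0.0119 in the same order, against the preset of 0.01.

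Genes of follicle rupture, prostaglandin action and matrix remodelling were called higher as a group in the high ovaries, in a test that depended on most libraries. All 5 tested members had a log2 difference above 0, with a median of 0.24 and a limma camera adjusted p of 0.0453. The call was lost with an estimated correlation (limma camera adjusted p = 0.463). The estimate was -0.144 for this list, below the preset of 0.01. Higher correlation among the members therefore does not account for the lost call. The unadjusted limma camera p rose from 0.0194 to 0.0756, and the cause was not tested. PTGFR, the receptor for prostaglandin F, was at 3.47 ± 1.44 against 1.79 ± 0.511, a log2 difference of 0.65. MMP7, a matrix metalloproteinase, was at 5.89 ± 6.21 against 2.02 ± 0.726, with 13.01 FPKM in high 1 alone. HPGD, which degrades prostaglandins, was at 11.1 ± 1.30 against 9.41 ± 2.23, and TIMP3, an inhibitor of metalloproteinases, at 109 ± 15.2 against 100.2 ± 23.5. PLAU, the urokinase gene, had a log2 difference of 0.029 (SE 0.298) while its mean was lower in high, at 38.8 ± 3.66 against 40.3 ± 16.8. HPGD turned to -0.049 with array weights. With a library left out the call was kept only without high 3 (limma camera adjusted p = 0.0253); the adjusted p was 0.393 without high 1, 0.0524 without high 2, and 0.302, 0.0790 and 0.134 without low 1, 2 and 3. It was 0.242 with array weights. High 1 stood highest in this list, with a mean deviation of 0.50, as it did for stromal and leukocyte markers, at 0.48 and 0.52, so the 3 calls are not independent of that library.

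Markers of stromal fibroblasts had a log2 difference above 0 for 6 of 6 tested members, with a median of 0.30 and a limma camera adjusted p of 0.0394. With an estimated correlation, which was 0.683 for this list against the preset of 0.01, the limma camera adjusted p was 0.638. The matrix protein gene DPT was at 91.8 ± 13.01 against 57.8 ± 31.4, a log2 difference of 0.77. The proteoglycan genes DCN and LUM were at 658 ± 91.0 against 527 ± 108 and at 72.4 ± 39.2 against 47.5 ± 20.2. PDGFRA, a receptor for platelet-derived growth factor, was at 38.5 ± 4.01 against 32.6 ± 8.09. ASPN had a log2 difference of 0.0066 (SE 0.363) while its mean was lower in high, at 41.0 ± 8.55 against 44.0 ± 22.1. The mean deviation of the members from their average over 6 libraries was 0.48, 0.15 and -0.12 in the high libraries and -0.66, -0.19 and 0.34 in the low libraries, so low 3 stood above high 2 and high 3. Without low 1, the library with the lowest stromal values, the limma camera adjusted p was 0.785.

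Leukocyte markers followed a similar order of libraries. Of 12 tested members 10 were higher in high ovaries, with a median log2 difference of 0.10 and a limma camera adjusted p of 0.0394. With an estimated correlation, which was 0.560 for this list against the preset of 0.01, the limma camera adjusted p was 0.656. JCHAIN, which joins secreted antibodies and marks plasma cells, was at 672 ± 587 against 232 ± 118, with 1348 FPKM in high 1 and 95.5 FPKM in low 1. CYBB, a subunit of the phagocyte oxidase, was at 11.6 ± 2.96 against 7.72 ± 2.77. SPI1, a myeloid transcription factor, was at 34.2 ± 6.66 against 24.0 ± 11.5, and the actin bundling gene LCP1 at 42.4 ± 8.97 against 33.3 ± 7.05. Mean deviations were 0.52, 0.16 and -0.22 in the high libraries and -0.56, -0.17 and 0.27 in the low libraries. Without low 1 the limma camera adjusted p was 0.785, and without high 1 it was 0.564.

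Members are counted as higher or lower by their log2 difference, and for 7 of the 98 tested entries (BOK, PLAU, ASPN, ZAR1L, MMRN1, TUBB1 and FGG) the means in FPKM differ in the opposite direction. In each of the 27 lists, 0 members passed the threshold over all genes tested and 0 passed when adjusted over the list alone by limma. Over all lists together, 3 members had an unadjusted limma p under 0.05. Of the 98 entries 64 changed direction with a library left out or with array weights, among them 2 of 5 for follicle rupture, 2 of 6 stromal and 7 of 12 leukocyte members. Of 7 lists with enough members, camera called 3, all 3 higher in high ovaries, while camera with an estimated correlation and fry each called 0. None of the 3 calls was made under median centring (limma camera adjusted p = 0.0528 for each) or quantile normalization, and with each library left out in turn the number of called lists ran from 0 to 4, with 0 without high 1, high 2, low 1 or low 2.

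**Figure D3:**
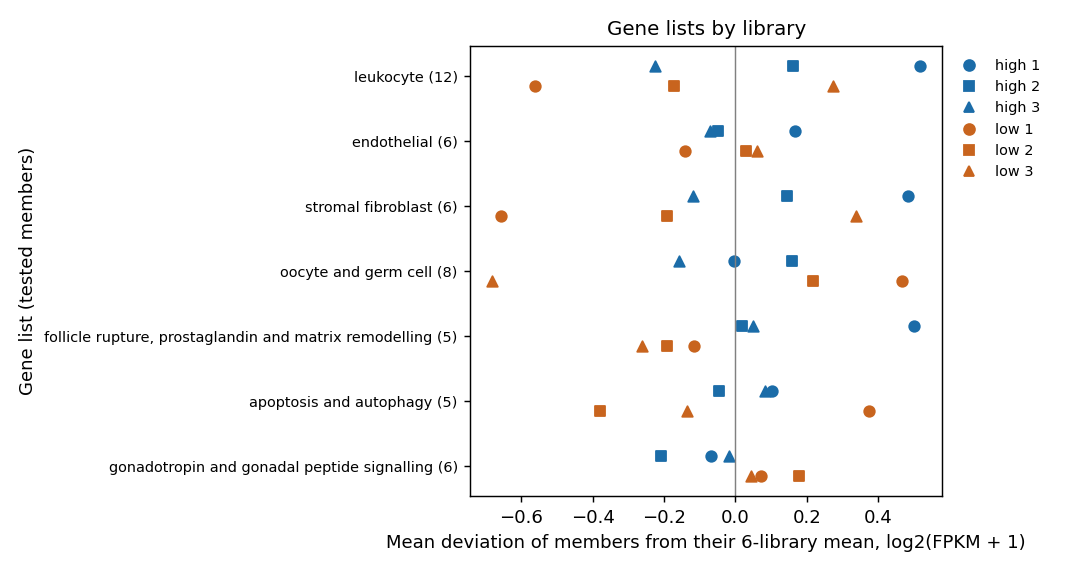
Mean deviation of the members of each tested gene list from their average over 6 libraries, in log2(FPKM + 1) on the horizontal axis; each point is 1 library, blue for high and orange for low production, and the number of tested members stands in brackets. Leukocyte and stromal fibroblast markers place low 1 lowest and high 1 highest, and the oocyte list places low 3 lowest at -0.68.

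Oocyte and germ cell genes were evenly divided, with 4 members higher and 4 lower, and the list was not called (limma camera adjusted p = 0.871). TDRD5, a germ cell RNA-pathway gene, was at 7.60 ± 1.98 against 10.01 ± 4.52. MOS, the kinase that holds eggs in meiotic arrest, was at 73.6 ± 16.0 against 64.1 ± 29.4, and BTG4, which acts in clearance of maternal RNA, at 269.6 ± 38.9 against 239.96 ± 126. Oocyte genes were low in low 3, with a mean deviation of -0.68 against 0.47 in low 1, and without low 3 the list was called lower in high ovaries (limma camera adjusted p = 0.00395). With an estimated correlation the limma camera adjusted p was 0.304 without low 3 and 0.950 with all 6 libraries. In some setting 7 of the 8 members changed direction. Endothelial markers had 3 members higher and 3 lower (limma camera adjusted p = 0.739), with PECAM1 at 53.9 ± 11.3 against 39.0 ± 5.398, VWF at 59.5 ± 5.58 against 54.6 ± 13.1, EMCN at 1.01 ± 0.508 against 1.45 ± 0.878 and TEK at 9.78 ± 1.98 against 10.6 ± 0.794. Apoptosis and autophagy genes had 3 higher and 2 lower (limma camera adjusted p = 0.739). Among them ATG5, a gene of autophagosome formation, was at 1.12 ± 0.526 against 1.70 ± 0.438 and BOK, of the BCL2 family, at 36.7 ± 4.44 against 37.6 ± 35.0, where the log2 difference of 0.42 differs in sign from the difference of the means.

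The other 20 lists had too few named members for a list test, and their values are descriptive. Of their 50 tested entries, 37 changed direction with a library left out or with array weights and 13 kept it. Those that kept it include all 3 ribosomal protein genes, higher in the high group with RPL7 at 1878 ± 162 against 1356 ± 210. For RPS7 and RPL15 the groups overlapped, with low 3 at 2400 and 1089 FPKM. COX7A2 of the respiratory chain also stayed higher in each fit (649 ± 34.9 against 469.9 ± 159), though low 1, at 653, was above high 2 and high 3. Both adipocyte genes stayed lower in each fit, with CIDEA at 57.2 ± 10.5 against 76.9 ± 20.6, though the groups overlapped. All 3 tested genes of cholesterol synthesis and uptake were higher, but each changed direction in some setting; NSDHL, at 11.6 ± 3.74 against 7.41 ± 7.50, turned to -0.41 with array weights. The single genes LYZ of oviduct gland (157 ± 68.7 against 119 ± 75.7), ESRP1 of surface epithelium (8.13 ± 2.68 against 7.70 ± 3.08) and the adrenal marker MC2R (3.33 ± 1.74 against 2.41 ± 2.19) were higher. LYZ turned to -0.13 without low 1, and ESRP1 and MC2R turned to -0.16 and -0.13 without low 3. Both tested genes of yolk uptake were lower, and both changed direction in some setting; RBP4, at 4.41 ± 0.396 against 6.45 ± 4.07, turned to 0.084 without low 1. All 3 nerve and glia genes were lower, but SOX10, at 1.95 ± 0.170 against 3.85 ± 3.53, and STMN2, at 28.7 FPKM in low 3, turned to 0.11 and 0.49 without low 3, and CNP turned to 0.14 without low 1.

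The remaining small lists were divided. Steroidogenic enzymes and theca cell markers each had 1 gene higher and 1 lower, and CYP19A1 stood first in both. Hormone receptor genes had 2 higher and 1 lower, with OXTR at 5.29 ± 1.04 against 4.43 ± 1.06, turning to -0.048 with array weights. Granulosa markers had 3 higher and 1 lower, with FSHR first. Cell cycle genes had 2 higher and 2 lower, with CCND1 at 18.9 ± 3.52 against 20.7 ± 5.59, turning to 0.083 without low 2. Collagen and matrix genes had 2 higher and 2 lower, with SPARC at 1691 ± 160 against 1364 ± 415, turning to -0.066 with array weights. Interferon response genes had 2 higher and 2 lower, and EPSTI1 was at 5.005 ± 1.93 against 2.32 ± 0.856 with an unadjusted limma p of 0.0295. Smooth muscle markers had 1 higher and 3 lower, with KCNMB1 at 167 ± 57.0 against 145 ± 62.7, turning to -0.069 without low 1. Erythroid and thrombocyte markers had 1 higher and 2 lower, with HEMGN at 4.11 ± 5.74 against 2.12 ± 1.69; HEMGN, the only one higher, was at 10.7 FPKM in high 3 and turned to -0.66 without it. Liver and yolk plasma proteins had 2 higher and 1 lower, with APOH at 5.53 ± 1.46 against 3.04 ± 1.30 and an unadjusted limma p of 0.0497. The list of immediate early and heat shock genes had 0 members with a name and was not analysed here.

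EXTL2 and CYB5R4 had large differences in single transcripts and smaller ones in the summed abundance of the gene's matched transcripts. Only 11.1% of all transcripts were matched, so others of these genes may be missing from the sums, the shares and the isoform test. The 3 main EXTL2 transcripts summed to 27.99 ± 3.69 FPKM in high and 27.5 ± 4.30 FPKM in low ovaries, counting another that was near 0. XM_005018759.2 made up 6.96% ± 1.84 of the EXTL2 sum in high and 52.7% ± 24.3 in low ovaries. XM_005018758.2 made up 57.8% ± 9.03 against 31.8% ± 16.1 of EXTL2, and XM_005018760.2 35.2% ± 9.06 against 14.9% ± 8.02. For CYB5R4, XM_005013063.2 made up 21.6% ± 2.42 of the gene's sum in high and 3.09% ± 0.119 in low ovaries, with sums of 27.1 ± 5.15 and 20.5 ± 1.29 FPKM. XM_005013060.2 of CYB5R4 was also higher in every high library than in every low one, at 5.24 ± 0.874 against 3.06 ± 1.55 FPKM. XM_005013064.2 of CYB5R4 was at 15.9 ± 4.36 against 16.8 ± 0.379 FPKM. For CMBL the sum also lay apart, at 8.61 ± 3.36 against 35.8 ± 24.5 FPKM, without passing the threshold (limma adjusted p = 0.997).

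Across 824 isoforms of 345 genes, limma called 1 changed share, CYB5R4 XM_005013063.2, higher in high by 1.98 in log2 odds (SE 0.242, limma adjusted p = 0.0426) and in every high library above every low library. At an unadjusted p under 0.05 there were 36 isoforms, where 41.2 would be expected with no difference. Leaving out 1 library gave between 0 and 2 called isoforms, and the CYB5R4 isoform was called in none of these 6 fits. The EXTL2 isoform was called only without low 3.

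**Figure D4:**
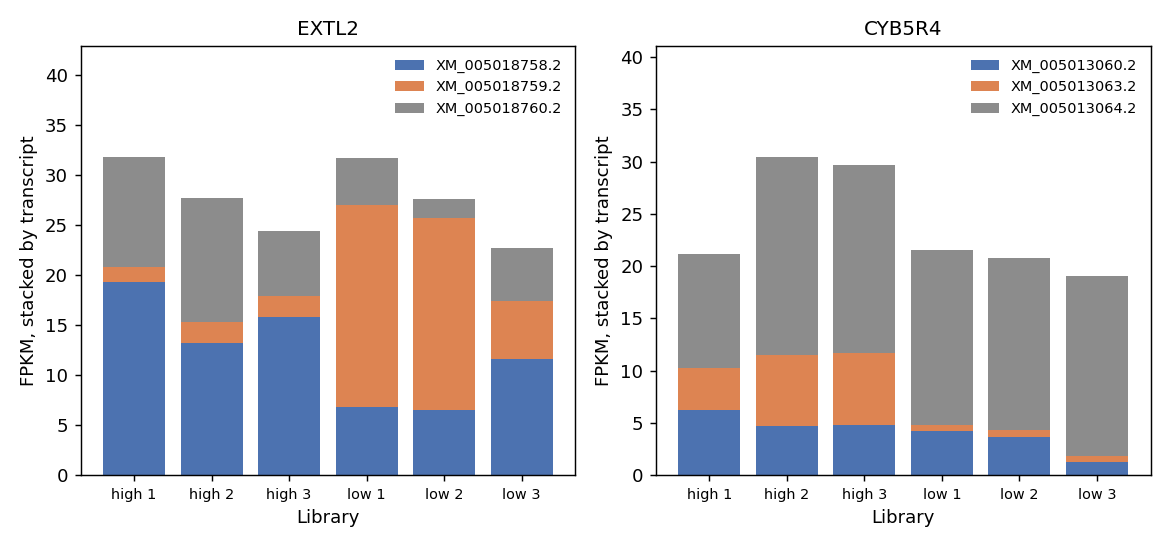
Abundance of the transcripts of EXTL2 and CYB5R4 in each of the 6 libraries, as stacked bars in FPKM from 0; each colour is 1 transcript, and an EXTL2 transcript of at most 0.420 FPKM in any library is not drawn. The EXTL2 bars are similar in height while XM_005018759.2 fills 6.96% of them on average in high and 52.7% in low ovaries.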

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

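No paired analysis was possible because the libraries of the groups share no replicate number in the labels. Depth is unknown, so precision rests on 3 libraries per group. Sums per gene, lists summed over transcripts, the alternatives for isoform shares, array weights with a library left out, estimated correlations by setting and directions of all list members were chosen after the data were examined; the other alternatives were fixed before. DESeq2, voom and the other alternatives for counts were not run, since the values are not counts. Robust estimation was not run for the gene lists.

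The count of 1 called transcript (0 higher, 1 lower) was also found without a variance trend, with quantile normalization, median centring, a minimum of 5 FPKM, a pseudocount of 0.1, robust estimation, a fold threshold and a threshold of 0.1. With no filter, and with a pseudocount of 0.01, limma called 0 transcripts, 0 of them lower; the unadjusted p of XM_013092159.1 rose from 3.97e-08 to 3.04e-06 unfiltered, so the larger number of tests is not the only reason, and its error rose to 1.23 with the pseudocount of 0.01. The causes were not tested. Sums per gene over named genes gave 0. Leaving out 1 library gave 1 to 3 called transcripts, 0 to 1 higher and 1 to 2 lower: 2 without high 1, low 1 or low 2, and 3 without low 3.

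Array weights gave 2292 called transcripts, 1115 higher and 1177 lower. The estimated weights were 0.846, 1.25 and 0.811 for the high and 0.251, 17.3 and 0.269 for the low libraries, so low 2 stood for almost its entire group. With array weights and 1 library left out the count fell to 7, 6 and 11 (high 1, 2 and 3) and to 2, 1 and 2 (low 1, 2 and 3). Whether such weights overfit 6 libraries in general was tested on the other splits of the libraries, which gave at most 19 called transcripts. No other split puts the 3 low libraries together, so this test cannot show whether the weights overfit the real grouping. The dependence on each library remains.

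The 3 called lists became 0 with array weights, quantile normalization, median centring, no filter, an estimated correlation and fry, and 0 to 4 with 1 library left out (0 without high 1, high 2, low 1 or low 2); the count was 3 with the other settings, though with a minimum of 5 FPKM the follicle rupture list had too few members and the gonadotropin list was called in its place, and without low 3 the oocyte list was. The cause was not tested. Isoforms with a changed share numbered 1 with a pseudocount of 0.1 and 0 to 2 with 1 library left out, 0 without each high library or low 2 and 2 without low 1. The similarity gap was 0.0328 with Pearson and 0.0357 with Spearman correlation.

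Of the values of named transcripts under all alternatives, 759 kept direction and side of the threshold, 21 newly passed it, 2 no longer passed and 29 changed direction, none of the last being called. With array weights the direction turned for OXTR (-0.048), NSDHL (-0.41), RBP4 (0.039), HPGD (-0.049), SPARC (-0.066) and LYZ (-0.013). With 1 library left out, log2 differences that changed direction ran from -0.11 to 0.17 for FST, -0.30 to 0.0039 for BMP7, -0.56 to 0.084 for RBP4, -0.27 to 0.083 for CCND1, -0.31 to 1.15 for BOK, -0.57 to 0.0084 for TDRD5, -0.083 to 0.61 for MOS, -0.18 to 0.69 for BTG4, -0.069 to 0.56 for KCNMB1, -0.047 to 0.30 for VWF, -0.22 to 0.038 for TEK, -0.66 to 0.72 for HEMGN, -0.13 to 1.03 for LYZ, -0.16 to 0.35 for ESRP1, -0.13 to 1.04 for MC2R and -0.98 to 0.11 for SOX10. The cause was not tested.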

Other observations

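The tests of isoforms against whole genes, of the called transcript, of the spread among low libraries and of splits for the gene count were chosen after the results were seen; the splits for lists and isoforms were set before their results. All splits are those of 6 libraries into 3 and 3, of which there are 10, too few for a share under 0.05.

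Low 1 and low 3, the pair least alike, differed in genes of particular cell types. Low 3 stood above low 1 by a median of 1.15 on the log2 scale for 4 smooth muscle markers, 1.01 for 6 stromal fibroblast markers, 0.88 for 12 leukocyte markers and 2.17 for 3 nerve and glia markers, of which 2 were higher. It stood below low 1 by a median difference of -1.22 for 8 oocyte genes, all 8 lower, and -1.68 for 3 plasma protein genes. Among abundant members, the smooth muscle actin gene ACTA2 was at 1154 FPKM in low 1 and 2510 FPKM in low 3, while the egg coat gene ZP2 was at 517 and 179 FPKM. JCHAIN was at 95.5 and 289 FPKM, the glial gene CNP at 33.1 and 17.2 FPKM, and the aromatase gene CYP19A1 at 39.9 and 12.8 FPKM. Collagen and matrix genes followed the stroma, with a median difference of 0.93.

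The lower similarity among low ovaries may reflect a different mix of follicles, stroma and muscle in the sampled pieces. Of 9 cell type lists with at least 3 tested members, 6 had a median difference between low 3 and low 1 outside the central 95% of 10000 random lists, 4 above and 2 below. If list members varied independently, 0.45 would be expected, and this pair was chosen as the least alike. Estimated correlations were 0.773 for oocyte, 0.683 for stromal, 0.560 for leukocyte and 0.037 for endothelial members, so 0.45 is not a fair chance level. The count of lists outside was 5 in each other low pair and 3 to 4 in pairs of high libraries, so such differences occur in both groups. They were larger in low pairs, with a median absolute list difference of 0.41 to 1.01 against 0.22 to 0.27 in high pairs, as the spread of transcripts in general was, and cell makeup, by laying rate or by the part of the ovary taken, stays open as the reason. Scaling of whole libraries by the authors is argued against, since rank correlation, which such scaling does not alter, kept a gap of 0.0357 between the groups. Scaling that differs between transcripts can alter ranks and was not tested. The 3 called lists include stroma and leukocytes, which are both highest in high 1 and lowest in low 1; the real split called 3 lists, the highest other split 3, and 3 of 10 splits gave as many.

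XM_013092159.1, near 0 in all 3 high libraries, may mark an inherited difference between the ducks, a difference in transcription tied to laying, or reads that the quantifier assigned to a similar transcript. For the last, 17 transcripts were higher in every high library than in every low one, with means apart by at least the 156 FPKM that this one was lower. Other labelings gave a median of 2 and at most 49 such transcripts, so partners of this size exist, fewer than in the labeling with the most. These explanations cannot be told apart without the sequences, which were not used here. The real split called 1 transcript, the highest other split 1, and 3 of 10 splits gave as many.

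For EXTL2 and CYB5R4 a difference of the whole gene as large as that of the isoform is argued against. Sums over matched transcripts differed by 0.036 (SE 0.194) for EXTL2 and 0.37 (SE 0.196) for CYB5R4 on the log2 scale, against -2.30 and 2.05 for the isoforms. A smaller rise of the whole CYB5R4 gene is not excluded by its sum. A candidate explanation is a change in splicing or transcript start, and another is that reads shared by overlapping transcripts were divided differently between libraries. The latter stays open, as does a sequence variant in some ducks, since no reads were used here. For isoform shares, the real split called 1, the highest other split 0, and 1 of 10 splits gave as many.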
